A study of Arabidopsis thaliana with 2 samples.

How the data were processed

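Total RNA from seedling shoots was sequenced from 1 wild-type (Col-0) library and 1 bts-1 library, prepared with a directional RNA sequencing kit after DNase treatment, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.12, TopHat2 2.1.0, Bowtie and HTSeq 0.9.1 and the genome build TAIR10, without saying in which order or with which settings they were used. Whether transcripts were selected by their poly(A) tail, and whether several plants or replicates were pooled, is not given in the sources used here. The deposited table holds 1 column of values per genotype for 18617 rows, each with an Arabidopsis gene identifier, most with a symbol and description.

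The deposited values are named as normalized FPKM (sequenced fragments scaled by transcript length and by the mapped reads of the library), but they are on a log2 scale. The lowest wild-type value is 0, and raising 2 to the power of the values, subtracting 1 and weighting by exon length gives sums of 1589846 in wild type and 1568061 in bts-1, above the value that the definition of FPKM implies but far closer to it than the 26824109 that a natural log would give; they were therefore read as log2(FPKM + 1). Sorted, the values of both columns are identical within 1e-06 at 79.9% of ranks and within 0.001 at 99.1%, as after quantile normalization between the libraries, a step that no label records. Such a step removes any overall difference in level between the libraries, and each ratio is relative to the other genes of the table. The design fixed before the data were examined had assumed FPKM on a linear scale with a pseudocount of 1; that pseudocount is already inside the deposited values, so the log2 ratio was taken as the difference between the columns. It understates the difference for genes of low level. A planned moderated test across replicate columns was not used because each genotype has 1 column.

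The lowest value is 0 in wild type, shared by 50 genes, and 0.15 in bts-1, shared by 123 genes. These genes were treated as not detected in that library, both values are given and no fold is stated for them, although they enter list medians and counts of genes. Among the genes at least 2-fold higher, 50 were at the lowest value of a library, and among those at least 2-fold lower, 85 were. The table gives no counts, so the depth is unknown and no counting interval can be given.

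2 rows carry an identifier with neither symbol nor description and were left out of all comparisons; they make up 4.33% of the summed FPKM in wild type and 4.34% in bts-1. The other 18615 rows comprise 18475 nuclear, 101 chloroplast and 39 mitochondrial genes, and 18510 had an FPKM of at least 1 in either library. A gene was counted as higher or lower at an absolute log2 ratio of at least 1. For each of 39 gene lists of 466 genes fixed before the data were examined, and for all genes of each organellar genome, the median log2 ratio was placed among 10000 random lists of nuclear genes, in which each member was replaced by one of its 50 nearest nuclear genes by mean log2 level. Lists with under 3 detected members were not placed. With 36 lists placed, 1.8 would be expected outside the central 95% by chance if genes within a list varied independently. Members that vary together can raise that number. Genes were named by a fixed rule: BTS, the 12 highest and 12 lowest nuclear genes by log2 ratio with an FPKM of at least 5 in either library, the 5 highest and 3 lowest of each organellar genome at that level, and up to 4 members of each list with the largest absolute ratios.

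The reference used here is the TAIR10.1 assembly with its gene annotation. As the builds differ by name, no coordinates are given. The reference served for gene types, exon lengths, gene order and the sequence alignments that follow. Exon lengths were found for 18455 of the 18615 genes. Mitochondrial exons were aligned to the nuclear chromosomes with BLAST+ 2.17.0; of 31 mitochondrial genes matched by symbol (out of 39), 10 had at least 90% of their exon sequence in the nuclear genome at 98% identity or more and 21 did not, and the alternative without nuclear copies used those 21. In the reverse direction, 33 nuclear genes of the table, all on chromosome 2, had at least 90% of their exon sequence in the mitochondrial genome.

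Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum FPKM of 5, ratios centred on the nuclear median, nuclear genes scaled to the same sum, the 200 nearest genes, the mean in place of the median, other fold thresholds and restricted organellar lists. Rescaling of chromosome 3 values, leaving out genes at the lowest values, leaving out chromosome 3 and keeping mitochondrial genes with under 50% of their exons in the nuclear genome were added after the data were seen. For the rescaling, each chromosome 3 value was multiplied by the exon length of the next gene in identifier order, long non-coding and antisense RNA genes skipped, and divided by its own exon length. The methods were tested on simulated data built from the 18370 nuclear genes. Of 1000 lists of 30 genes without a difference, 6.8% were called apart, and of 1000 lists shifted by 0.5 on the log2 scale, 100% were. Each simulated list was placed among 1000 random lists. Most fixed lists hold fewer than 30 detected genes and have wider random ranges. That of 3 mitochondrial ribosomal protein genes was -0.63 to 0.58, wider than the planted shift. The simulated genes also varied independently, so these rates do not carry over to shorter lists or to lists whose members vary together. Of 200 genes with little difference beforehand that were then changed 3-fold, 100% were counted at the 2-fold threshold. The change was added directly to the ratio, so this outcome was fixed and checks the counting only. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.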

Results

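Shoots of Arabidopsis thaliana seedlings were profiled by RNA sequencing in wild-type plants of the Col-0 accession and in the bts-1 mutant, both grown on Murashige and Skoog medium without sucrose. BTS (BRUTUS) encodes an E3 ubiquitin ligase that limits the response of the plant to iron deficiency. The question named by the series is how BTS relates to cellular energy and to the expression of genes carried by the chloroplast and mitochondrial genomes. Each genotype had 1 library, so no p-value, standard deviation or replicate check can be given, and every difference below compares 2 libraries. Values are log2(FPKM + 1) as deposited, and a log2 ratio is the bts-1 value minus the wild-type value. The read depth of the libraries is unknown because the values hold no counts. A gene list is called apart when its median lies outside the central 95% of 10000 random nuclear lists matched on expression level, which describes these libraries only.

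BTS itself (AT3G18290, chromosome 3) was lower in the bts-1 library, at 9.57 against 10.84 in wild type, a log2 ratio of -1.27. The listed wild-type level exceeded that of 99.8% of the genes in the table. Levels of chromosome 3 genes are uncertain, since on this chromosome the level varied with the exon length of the next gene (slope -0.57, SE 0.03, against -0.02 to 0.05 on the other chromosomes). With chromosome 3 values rescaled by exon lengths, a setting chosen after the data were seen, BTS stood at 5.38 in bts-1 and 6.63 in wild type and its log2 ratio was -1.25. The same uncertainty holds for the level of every chromosome 3 gene named below, recognisable by an identifier that begins with AT3G.

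Among 18510 genes with an FPKM of at least 1 in either library, 356 were at least 2-fold higher and 672 at least 2-fold lower in bts-1. Among those with an FPKM of at least 5 in either library, the nuclear gene with the highest ratio outside non-coding and uncharacterised loci was AT5G24240, annotated as a phosphatidylinositol kinase and ubiquitin family protein, at 0.04 in wild type and 2.74 in bts-1. MIOX2 (AT2G19800), a myo-inositol oxygenase, stood at 4.76 in wild type and 7.06 in bts-1, and UGT85A4 (AT1G78270), a UDP-glucosyl transferase, was higher by 2.22. PORB (AT4G27440), a light-dependent enzyme of chlorophyll synthesis, was higher by 1.88, EBF2 (AT5G25350), an F-box protein that targets the ethylene signalling factor EIN3, by 1.87, and the transcription factor gene bHLH87 (AT3G21330) by 1.95. At the other end, PR1 (AT2G14610), a marker of salicylic acid signalling, stood at 3.99 in wild type and at the lowest value of the bts-1 library, and EXLA3 (AT3G45960), an expansin-like gene, at 3.86 and again at that lowest value. SAG13 (AT2G29350) had a log2 ratio of -3.64, the receptor-like protein genes RLP41 (AT3G25010) and RLP38 (AT3G23120) of -3.63 and -3.58, and JAZ7 (AT2G34600), a repressor of jasmonate signalling, of -3.50. The late embryogenesis abundant family gene AT1G52690 was at -3.54, the ethylene response factor gene AT5G51190 at -3.42, TAT3 (AT2G24850) at -3.34, PCC1 (AT3G22231) at -3.20, UGT76E12 (AT3G46660) at -3.17 and PR2 (AT3G57260), a beta-1,3-glucanase, at -3.12. Of the other 6 genes in the highest 12, AT2G07763, AT2G07830, AT2G07747 and AT2G07792 lie among 33 chromosome 2 genes whose exons match the mitochondrial genome, so their reads cannot be assigned with certainty. The remaining members, the non-coding RNA AT1G03506 and the uncharacterised AT5G66607, were listed at 0 in wild type and at 3.20 and 3.15 in bts-1. The counts depended on the pseudocount: with 0.1 in place of 1 they were 735 higher and 997 lower, and with 5 they were 101 and 254.

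Transcripts of the chloroplast genome were higher in bts-1 as a group. The median log2 ratio of 101 chloroplast genes was 1.00, against -0.07 to 0.06 for matched random lists, with 50 genes at least 2-fold higher and 4 at least 2-fold lower. The summed FPKM of these genes was 10534 in wild type and 21085 in bts-1. Among genes with an FPKM of at least 5 in either library the highest ratios were those of trnG (ATCG00310), listed at 0 in wild type and at 2.59 in bts-1, and of psbH, petD, ndhE and trnL (ATCG00400), the last at 8.11 and 9.63. The cytochrome b6f complex, which carries electrons between the photosystems, had all 6 genes at least 2-fold higher (median 1.17), among them petD (ATCG00730) at 6.93 in wild type and 8.49 in bts-1 and petB (ATCG00720) at 7.12 and 8.61. Photosystem II had 9 of 15 genes at least 2-fold higher (median 1.19), led by psbH (ATCG00710) at 6.28 and 7.89 and psbD (ATCG00270) at 7.26 and 8.65. Photosystem I had 3 of 5 genes past that size (median 1.23), with psaC (ATCG01060), psaB (ATCG00340) and psaA (ATCG00350) higher by 1.31, 1.24 and 1.23. The NDH complex, which feeds electrons back into the chain, had 6 of 10 (median 1.11), including ndhE (ATCG01070) at 5.93 and 7.47, and ATP synthase had 4 of 6 (median 1.02), including atpH (ATCG00140) at 7.73 and 8.81. The ratios were smaller for the plastid RNA polymerase, with 0 of 4 genes past 2-fold and a median of 0.69, and for ribosomal proteins, with 2 of 17 past 2-fold and a median of 0.77. Each of these 7 lists lay above its random lists, which draw nuclear genes independently. The 4 ATP synthase genes past 2-fold, atpA, atpF, atpH and atpI, are neighbours by identifier, with ratios of 1.01 to 1.08. In that list atpB and atpE, named after their values were seen, were at 0.43 and 0.30. Whether neighbouring chloroplast genes vary together was not tested, so the genes counted may not be separate observations. The lowest chloroplast genes with an FPKM of at least 5 in either library were non-coding, with log2 ratios of -1.25 for the 23S rRNA gene ATCG00950, -0.58 for trnR (ATCG00110) and -0.36 for trnY (ATCG00240). The second copy of the 23S rRNA gene, ATCG01180, had a ratio of 0.90, and reads of such repeated genes cannot be assigned with certainty; it is named after its value was seen.

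Mitochondrial genome transcripts were also higher in bts-1, at lower levels than those of the chloroplast. The median log2 ratio of 39 genes was 0.87, against -0.11 to 0.22 for random lists, with 12 genes at least 2-fold higher and 0 at least 2-fold lower, and the summed FPKM was 1035 in wild type and 2002 in bts-1. Most of that sum came from the rRNA genes rrn26 (ATMG00020), at 8.81 and 9.78, and rrn18 (ATMG01390), at 8.79 and 9.67, named after their values were seen. Complex I of the respiratory chain had 7 of 11 listed loci at least 2-fold higher (median 1.16), some of them separate exon loci of the same gene (nad1, nad2 and nad5). The nad1 loci ATMG01130, ATMG01200 and ATMG01220 and the nad2 locus ATMG01330, outside that list and named after their values were seen, had log2 ratios of 0.62, 0.73, 0.45 and 1.21. Within the list nad4L (ATMG00650) stood at 3.50 in wild type and 4.87 in bts-1, and the nad1 exon locus ATMG01120 at 2.03 and 3.43. The nad5 locus ATMG00665 was listed at 0 in wild type and at 5.07 in bts-1. Complexes III and IV had a median of 0.82 over 3 genes, led by cox1 (ATMG01360) at 3.32 and 4.46. ATP synthase had a median of 0.72 over 4 genes and ribosomal proteins of 0.87 over 3, led by orf25 (ATMG00640), higher by 1.09, and rps3 (ATMG00090), at 2.61 and 3.74. The lowest genes, at that same minimum level, were the 5S rRNA gene rrn5 (ATMG01380), at -0.77, the hypothetical gene ArthMp059 (ATMG00660), at 0.13, and atp9 (ATMG01080), at 0.58. All 4 of these lists lay above their random lists, except that the ribosomal protein list did not when its mean replaced its median (0.66). Cytochrome c maturation had 1 detected gene, ccb203 (ATMG00960), at 0.60 and 1.49, too few for a list. Mitochondrial genes share sequence with chromosome 2, and the 21 genes without a near-identical nuclear copy over at least 90% of their exons had a median of 0.88. Some of these match the nuclear genome over a smaller share, and the 11 genes with under 50% of their exons matched, a limit chosen after the data were seen, had a median of 0.97.

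**Figure D1:**
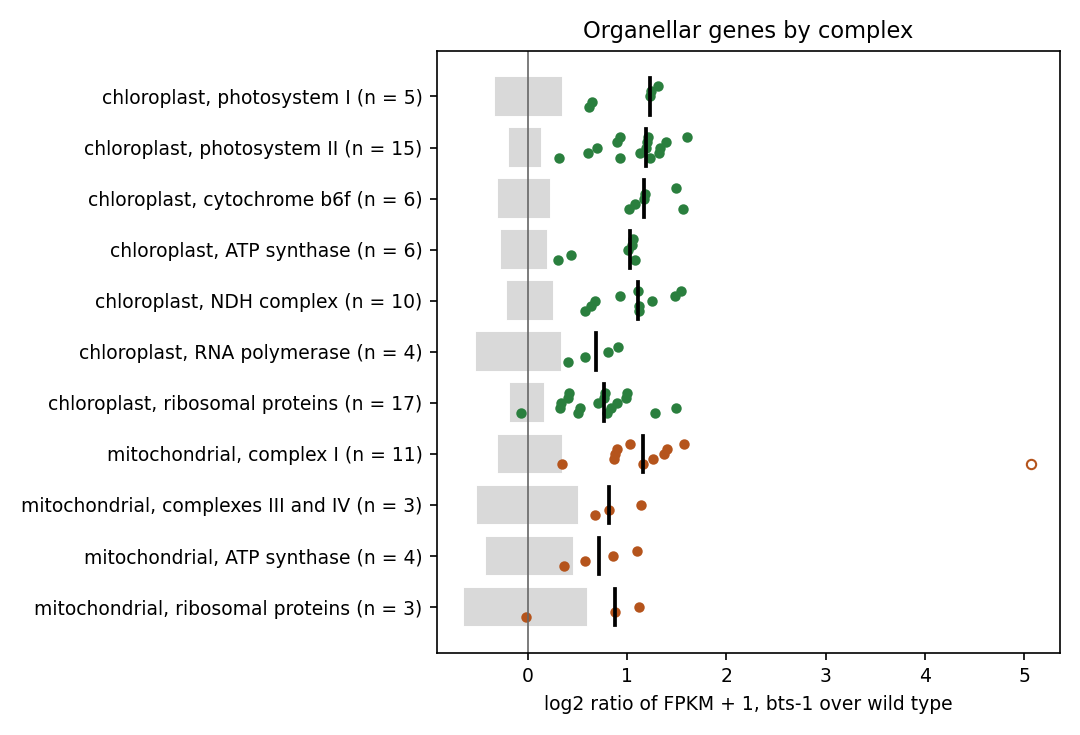
Log2 ratio of FPKM + 1 (bts-1 over wild type, horizontal axis) for each detected gene or exon locus of 11 organellar gene lists, 1 point each. Green points are chloroplast genes, brown points mitochondrial genes, the open point is the nad5 locus listed at 0 in wild type, black bars are list medians and grey boxes the central 95% of medians of 10000 matched random lists; all 11 medians lie to the right of their grey box.

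Nuclear genes for the same machineries did not follow the organellar genes in size. The 37 nuclear subunits of oxidative phosphorylation had a median log2 ratio of -0.01, inside the random range of -0.09 to 0.12, with 0 genes past 2-fold in either direction. The largest ratio in that list was -0.95 for the cytochrome c gene CYTC-2 (AT4G10040), followed by -0.36 for CYTC-1 (AT1G22840). For the 37 nuclear subunits of the photosystems, electron transport and Rubisco the median was 0.08, just above the random range of -0.13 to 0.07, and 0 genes passed 2-fold. PSBQ2 (AT4G05180) was higher by 0.50 and FD2 (AT1G60950), the major leaf ferredoxin, by 0.40, while FD1 (AT1G10960) had a log2 ratio of -0.49. This list was no longer apart when its mean was used (0.06), when chromosome 3 values were rescaled (0.08) or when chromosome 3 genes were left out (0.09). The 20 light-harvesting protein genes had a median of 0.27, above the random range of -0.17 to 0.08, and 18 of 20 had a positive ratio. LHCB1.4 (AT2G34430) stood at 8.96 in wild type and 10.34 in bts-1, the one member past 2-fold, although near-identical LHCB1 copies can share reads. Chlorophyll synthesis genes were apart as well (20 genes, median 0.14, random range -0.15 to 0.12), with PORB the one member past 2-fold, followed by HEME1 (AT3G14930), higher by 0.57. The nuclear genes for plastid transcription were not apart (18 genes, median -0.09), and SIG5 (AT5G24120), a sigma factor responsive to light and stress, stood at 6.60 in wild type and 5.60 in bts-1. Neither were those of the tricarboxylic acid cycle (12 genes, median -0.01), where FUM1 (AT2G47510) was at 0.45 and MMDH1 (AT1G53240) at -0.39. The mitochondrial RNA polymerase genes RPOTM (AT1G68990) and RPOTMP (AT5G15700), too few for a list, had log2 ratios of -0.20 and 0.12.

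Genes induced by iron deficiency were higher in bts-1 as a group, and so were genes of iron storage. Of 27 detected iron-deficiency genes, 10 were at least 2-fold higher and 1 at least 2-fold lower, with a median log2 ratio of 0.41 against a random range of -0.13 to 0.20. IRT1 (AT4G19690), the main iron uptake transporter of the root, stood at 1.31 in wild type and 2.97 in bts-1. NAS2 (AT5G56080), a nicotianamine synthase, stood at 0.27 and 2.06, CYP82C4 (AT4G31940), which acts in the synthesis of iron-mobilising coumarins, was higher by 1.62, and the regulator gene BHLH38 (AT3G56970) stood at 2.18 and 3.77. IMA3 (AT2G30766), which encodes a small peptide that promotes iron uptake, went the other way, at 5.08 and 3.87; it is the 1 member at least 2-fold lower and is named after its value was seen. Many of these genes were near the low end of expression. Among the 19 members with an FPKM of at least 5 in either library the median was 0.17 and no longer apart. In the whole list, 20 ratios were positive and 7 negative. Every member above a log2 level of 5 in wild type, a limit chosen after the data were seen, had a negative ratio. Besides IMA3 these were CGLD27 (AT5G67370) at -0.62, ORG1 (AT5G53450) at -0.29, NAS1 (AT5G04950) at -0.19, FRO3 (AT1G23020) at -0.18 and OPT3 (AT4G16370) at -0.11. Several members of the iron-deficiency list are root genes. Of 12 root markers, 3 were detected in these shoots, all with positive log2 ratios. PHT1;1 (AT5G43350) was at 0.56, CASP1 (AT2G36100) at 0.41 and PYK10 (AT3G09260), listed at 10.06 in wild type and 10.19 in bts-1, at 0.13. Their median of 0.41 lay inside the random range of -0.59 to 0.52. That range is wide enough to hold a median as large as that of the iron-deficiency genes, so a difference in root markers is not excluded. The 5 seed and embryo markers have no entry in the deposited table. Whether they were undetected or left out is not known, so no value is given for them.

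The 9 detected iron storage and iron-excess genes had a median log2 ratio of 0.44 against a random range of -0.31 to 0.29, and 7 of 9 were positive with 0 past 2-fold. The ferritin genes, whose proteins store iron in plastids, were all higher: FER4 (AT2G40300) by 0.96, FER1 (AT5G01600) with 7.17 in wild type and 7.87 in bts-1, FER2 (AT3G11050) with 1.19 and 1.83, and FER3 (AT3G56090), outside the naming rule, with 3.39 and 3.76. VTL1 (AT1G21140), a vacuolar iron transporter homologue, was higher by 0.76. The 5 bHLH regulators that act upstream of this response, BHLH104, ILR3, BHLH115 and BHLH34 of subgroup IVc and URI of subgroup IVb, were not apart (median -0.05), with BHLH34 (AT3G23210) at -0.49 and URI (AT3G19860) at 0.44. Iron-sulfur cluster assembly genes were not apart (12 genes, median -0.02), with NEET (AT5G51720) at 0.45 and SUFB (AT4G04770) at 0.36. Zinc and copper deficiency genes were not apart either (7 genes, median 0.20), although the copper transporter gene COPT2 (AT3G46900) was at 5.72 in wild type and 4.56 in bts-1 and the iron superoxide dismutase gene FSD1 (AT4G25100) was higher by 0.57.

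**Figure D2:**
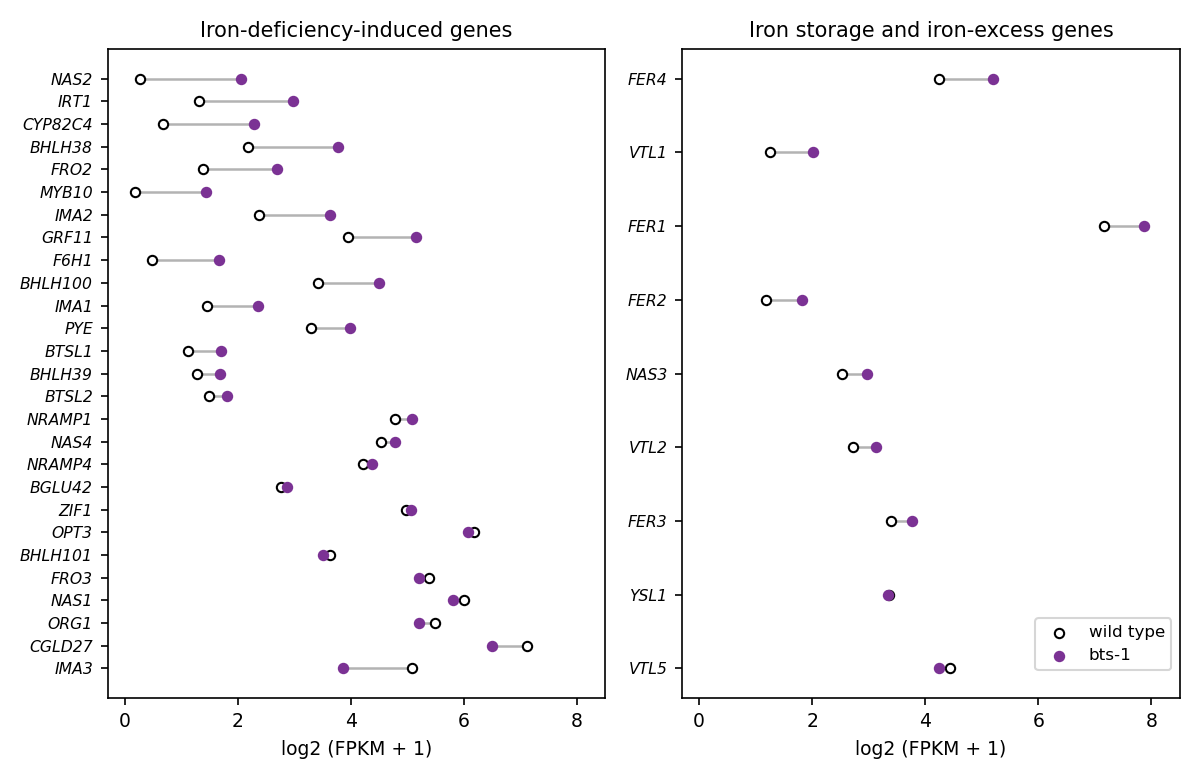
Log2(FPKM + 1) in the wild-type library (open circles) and the bts-1 library (filled circles) for each detected member of the list of iron-deficiency-induced genes (left, 27 genes) and of the list of iron storage and iron-excess genes (right, 9 genes), ordered by log2 ratio. A grey line joins the 2 values of a gene; 20 of 27 and 7 of 9 genes have the filled circle to the right.

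Low-energy and dark-induced genes, which respond to sugar and light shortage, were higher in bts-1, with 8 of 14 at least 2-fold higher and a median log2 ratio of 1.02 against a random range of -0.18 to 0.16. Besides MIOX2, DRM2 (AT2G33830) was higher by 1.74, the asparagine synthetase gene DIN6 (AT3G47340) stood at 11.05 in wild type and 12.58 in bts-1, and SEN1 (AT4G35770) at 7.35 and 8.67. In contrast, stress and defence lists were lower. The salicylic acid and immune list had 8 of 11 genes at least 2-fold lower (median -1.57), including WRKY33 (AT2G38470) at 6.37 and 3.68 and WRKY40 (AT1G80840) at 4.23 and 2.45. Heat shock genes had 4 of 5 at least 2-fold lower (median -1.60), with HSP90.1 (AT5G52640) at 5.67 and 3.26 and HSP17.4 (AT3G46230) at 2.99 and 0.87. Abscisic acid, cold and drought genes had 4 of 6 at least 2-fold lower (median -1.14), with RD29B (AT5G52300) at 4.16 and 1.31 and KIN2 (AT5G15970) at 5.33 and 3.88. Alternative respiration and mitochondrial stress genes had 4 of 11 at least 2-fold lower (median -0.81): the alternative oxidase gene AOX1D (AT1G32350) stood at 2.83 in wild type and at the lowest value of the bts-1 library, DIC2 (AT4G24570) at 5.01 and 2.57, OM66 (AT3G50930) at 3.36 and 1.08, and HSP23.5 (AT5G51440) at 5.09 and 3.27. Each of these 4 lists lay below its random lists, whose lowest bound was -0.40. Jasmonate response genes had a median of -0.26, just below the random range of -0.25 to 0.32 and inside it under 4 alternatives, such as without chromosome 3 genes (-0.17), with JAZ1 (AT1G19180) at 4.75 and 2.47. Anthocyanin synthesis genes were lower (6 genes, median -0.63, random range -0.30 to 0.34), with F3H (AT3G51240) at -0.97, the regulator gene PAP1 (AT1G56650) at -0.93 and 0 genes past 2-fold.

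Among the remaining lists, antioxidant enzymes had a median log2 ratio of 0.19, just above the random range of -0.17 to 0.18, and were not apart with the mean (0.16), with 200 nearest genes or without chromosome 3 genes. Its members went both ways, with the catalase genes CAT1 (AT1G20630) and CAT3 (AT1G20620) at 1.09 and 0.79 and CAT2 (AT4G35090) at -0.55. Phosphate starvation genes were not apart (5 genes, median -0.40, random range -0.45 to 0.46), with ACP5 (AT3G17790) at -1.68 and SPX1 (AT5G20150) at -1.29; they lay below the random lists with the mean (-0.67), at a minimum FPKM of 5 and with chromosome 3 values rescaled. Senescence and chlorophyll breakdown genes were not apart (7 genes, median -0.10), except with the mean (-0.52), and SAG13 is the 1 member past 2-fold. Morning-phased clock genes were lower (8 genes, median -0.44, random range -0.23 to 0.27), with RVE1 (AT5G17300) at -0.79, LHY (AT1G01060) at -0.50 and PRR7 (AT5G02810) at 0.74. Evening-phased clock genes were not apart (5 genes, median 0.15), with ELF3 (AT2G25930) at 0.43 and LUX (AT3G46640) at 0.35. The 13 reference genes had a median of 0.00, with UBQ10 (AT4G05320) at 0.59 and GAPC2 (AT1G13440) at -0.34. In all, 25 of the 36 lists with at least 3 detected genes were apart, 18 higher and 7 lower.

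**Figure D3:**
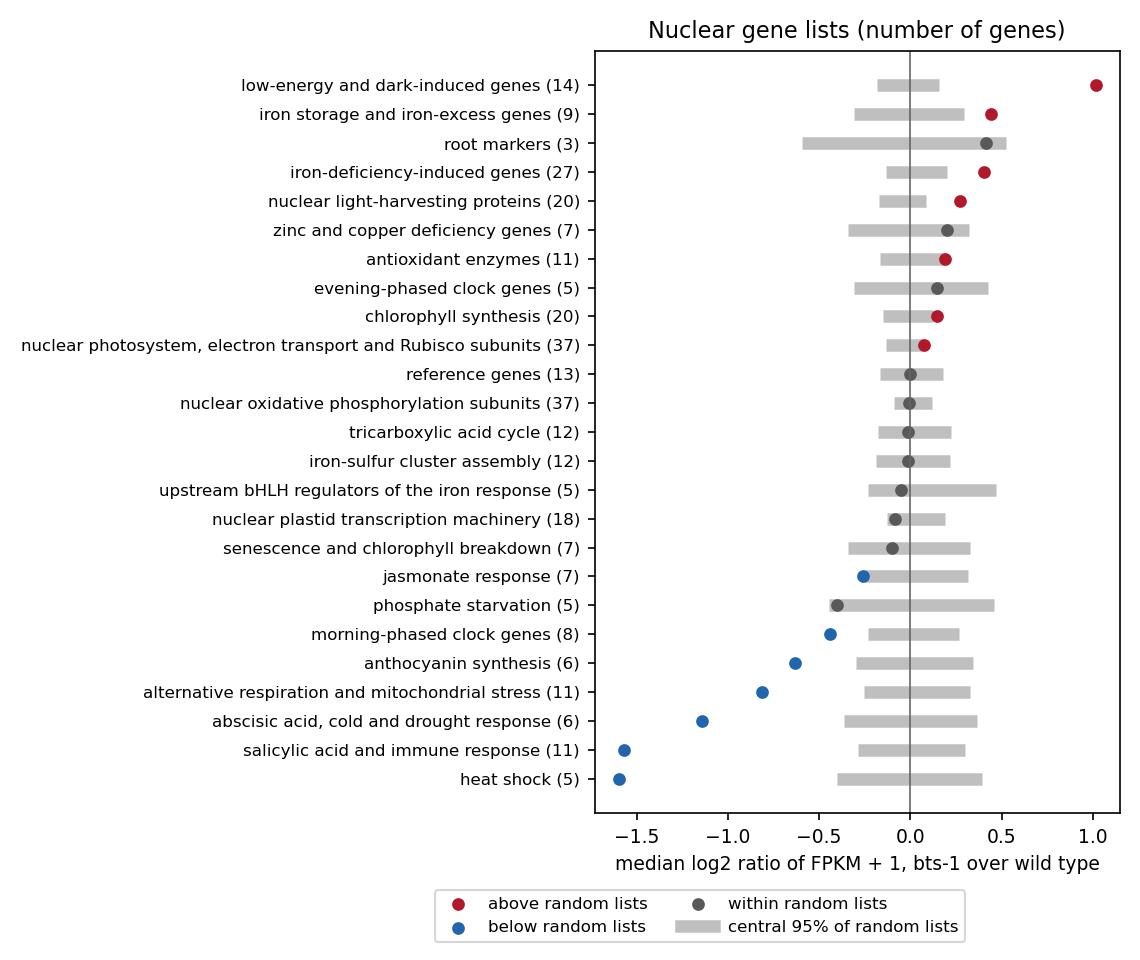
Median log2 ratio of FPKM + 1 (bts-1 over wild type, horizontal axis) of each nuclear gene list with at least 3 detected genes, with the number of genes in brackets. Grey bars span the central 95% of medians of 10000 random nuclear lists matched on level; red points lie above, blue points below and grey points within that span, from low-energy genes at 1.02 to heat shock genes at -1.60.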

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

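The row AT2G00000, which has neither symbol nor description and enters no comparison, stood at 5.15 in wild type and 6.23 in bts-1, a log2 ratio of 1.08. It is given here because its signal lies outside the compared genes and was above that in the wild-type library; it was not tested further. The other row of this kind, AT3G00000, had the highest value of the table, 15.17 in both libraries.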

How the results depend on the processing

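The 4 alternatives concerning chromosome 3, genes at the lowest values and mitochondrial genes with under 50% of their exons in the nuclear genome were chosen after the data were seen. BTS was lower in bts-1 under each alternative run for it, and the medians of both organellar genomes, of the iron storage genes and of nuclear oxidative phosphorylation stayed on their side of the random lists under every alternative run for them. The count of genes at least 2-fold higher was 735 with a pseudocount of 0.1, 101 with a pseudocount of 5 and 198 at a minimum FPKM of 5; at thresholds of 1.5-fold and 3-fold it was 1394 and 50. The count of lower genes was 254 with a pseudocount of 5, and 1726 and 213 at the 1.5-fold and 3-fold thresholds. A larger pseudocount shrinks ratios of low genes by construction. The iron-deficiency median was 0.17 and inside the random lists at a minimum FPKM of 5, where 19 of 27 genes are left. The median of nuclear photosystem, electron transport and Rubisco subunits was no longer apart with the mean (0.0641), with rescaled chromosome 3 values (0.0751) or without chromosome 3 genes (0.0881); the cause was not tested. Between 22 and 25 lists were apart across settings, with at least 22 of the same lists in the same direction in each. At a minimum FPKM of 5 and without chromosome 3 genes, 34 and 35 of 36 lists had enough genes for a value. Among the other 32 lists, 8 values of 349 lost their call and 4 gained one, in 5 lists. Of 1495 values for the other 172 named genes, 56 moved by over 1.5-fold, in 34 genes, and 0 called values changed sign. Leaving out replicate columns was not applicable with 1 column per genotype. No paired analysis was possible because each genotype has 1 library. The unknown depth leaves the counting error of low genes open.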

Other observations

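Gene families drawn from the words of the gene descriptions, and the tests of explanations in this part, were chosen after the data were seen; the organellar, clock and stress lists themselves were fixed earlier. Of 22 families, 2 were higher, 11 lower and 9 not apart. Of 40 SAUR genes, which respond early to auxin, 32 had a positive log2 ratio and 7 were at least 2-fold higher (median 0.43, random range -0.14 to 0.18), with AT4G38860 at 4.08 in wild type and 5.93 in bts-1 and AT3G12830 at 3.73 and 5.56. The 19 Aux/IAA genes had a median of 0.24 (random range -0.15 to 0.18), which was not apart without chromosome 3 genes.

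Glutathione S-transferases were lower in bts-1 and had a median of -0.57 over 41 genes, with 8 at least 2-fold lower, among them GSTU24 (AT1G17170) at 5.72 in wild type and 3.59 in bts-1. UDP-glycosyltransferases (68 genes, median -0.21) and cytochromes P450 (106 genes, median -0.23) were lower too, with CYP81D8 (AT4G37370) at 4.61 and 1.90. Calmodulin-like genes had a median of -0.53 over 29 genes, with the touch-induced TCH2 (AT5G37770) at 6.68 and 5.10, cysteine-rich receptor-like kinases of -0.48 over 26 and heat shock proteins of -0.39 over 39, with HSP70 (AT3G12580) at 12.17 and 9.42. NAC factors (44 genes, median -0.20), disease resistance proteins (94 genes, median -0.06) and cytosolic ribosomal proteins (196 genes, median -0.08, 0 past 2-fold) were lower as well. Receptor-like proteins (median -0.27 over 34) and lipid transfer proteins (-0.21 over 52) were lower, but not apart without chromosome 3 genes. WRKY factors, ethylene response factors, MYB factors, expansins, xyloglucan endotransglucosylases, peroxidases, aquaporins, histones and pentatricopeptide repeat proteins were not apart, except ethylene response factors without chromosome 3 genes. Among them, 9 of 44 WRKY genes and 11 of 66 ethylene response factor genes were at least 2-fold lower, with 0 and 1 at least 2-fold higher. The 33 chromosome 2 genes that match the mitochondrial genome had a median of 0.75 (random range -0.17 to 0.27), with 12 at least 2-fold higher and 0 at least 2-fold lower, beside 0.87 for the mitochondrial genes; whether reads were shared was not tested.

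Organellar transcripts were higher in bts-1 by a median of 1.00 for the chloroplast and 0.87 for the mitochondrion. An offset from normalization cannot be told apart from an effect of genotype: both medians exceeded the upper end of nuclear lists matched on level, the smaller gap being 0.66, but nuclear medians near 0 are fixed once both libraries have nearly the same distribution of values. An even addition of organellar DNA was argued against for the chloroplast only if FPKM differences stay additive, which quantile normalization need not preserve. The FPKM added per protein-coding gene was 13.4 times as large at the 90th percentile (238) as at the 10th (17.8). These percentiles cover the 62 of 63 genes with a higher FPKM in bts-1. More RNA without a poly(A) tail in the bts-1 library cannot be told apart from an effect of genotype. The 37 snRNA and snoRNA genes went the opposite way (median -0.37, below the random range of -0.15 to 0.25, with 15 positive). In contrast, 3 nuclear rRNA loci had a median of 0.58. Only rRNA loci below the highest value of a named gene, 14.58 in both libraries, were used for that median. The genotype stays open as an untested explanation, with 1 library each.

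Stress and defence genes were lower in bts-1. An effect of the floor on low values was argued against for the immune, abscisic acid and alternative respiration lists: among genes with an FPKM of at least 5 in both libraries (5, 3 and 4 genes) their medians were -1.36, -1.04 and -0.53, each below its random lists, with a smallest gap of -0.17. It was argued against for heat shock genes at a lower limit, as 1 of them reached that level: the 4 with an FPKM of at least 1 in both libraries had a median of -1.49, below their random lists by a gap of -1.01. A different time of day at harvest cannot be told apart from genotype, because morning-phased clock genes were lower (median -0.44) while evening-phased genes were not apart (median 0.15). A stress met by the wild-type plants alone, or an effect of the mutation, may also underlie the pattern, and neither was tested.

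Levels on chromosome 3 were unusually high: 4.60% of its genes had a mean log2 level above 8, against 1.19% to 1.69% on the other chromosomes. A candidate explanation is that each value was divided by the exon length of the next gene. On chromosome 3 the slope of level on the log2 exon length of the next gene was -0.57. The lowest slope at 119 other offsets on that chromosome was -0.06, and the slopes on other chromosomes lay between -0.02 and 0.05. The same error planted on another chromosome in simulated data gave a steeper slope, -0.86. That error was added directly to the log2 level, with the same exon lengths and gene order as the fit. The difference in slope therefore cannot decide whether the full error, which the rescaling of chromosome 3 values assumes, is present. More transcripts from chromosome 3 as a whole would not alone produce the slope on a gene's own exon length. That slope exceeded that of every other chromosome by at least 0.54. An even excess of transcripts would leave it unchanged, so the slope cannot exclude such an excess in addition. Values listed under a neighbouring gene were argued against, since 7 of 7 abundant photosynthesis genes of chromosome 3 lay above both neighbours in the table.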
